A study of Mus musculus with 24 samples.

How the data were processed

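Brain and liver of newborn female mice were measured on 24 single-colour arrays, 4 for each of 3 groups (NC, CC and G20) in each tissue. Per the labels, RNA was extracted with Trizol and cleaned on columns, and Cy3-labelled cRNA was made from it by a low-input amplification for single-colour arrays. Per the file headers, the scanner's intensity values were extracted with Agilent Feature Extraction 9.5.3.1, which subtracted background, removed spatial and multiplicative trends and replaced very low values with surrogates, and which did not normalize between arrays. The flags for each spot (well above background, saturated, outlier) are values of another kind, 0 or 1, written by the same program per the file headers. The deposited series matrix holds linear intensities on an unlogged scale, with nothing where a probe was not well above background, and how the authors scaled them is not given in the sources used here.

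The deposited matrix was set against the scanner values of the same arrays. Its 34140 probes were all found in the scanner files. Column medians were 353.8 to 392.8 in NC and G20 brain, 223.6 to 282.8 in NC and G20 liver, 463.1 to 489.5 in CC brain and 299.9 to 341.3 in CC liver. NC and G20 columns equalled the scanner's processed signal times about one factor per array, with an SD of the log2 ratio over probes of 0.0103 to 0.0554. CC columns carried a further factor for each probe, shared by the 4 CC arrays of a tissue, with an SD of 0.627 to 0.657. Where this factor comes from is not given in the sources used here, so the linear scale of the matrix is known and its centring is not. The scanner files were therefore used for all comparisons, and the matrix values served as an alternative. The number of columns left unused in the matrix was 0.

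Each scanner file held 43379 spots other than controls, for 41174 probes. Spots marked as outliers by the scanner software were removed, and replicate spots of a probe were averaged on the log2 scale. Processed signal was put on the log2 scale and each array was centred on its 75th percentile. Probes were named through their accession where a reference table of gene names held it (23374 probes), and the others kept the name in the file (17800 probes). The arrays gave 27845 gene names, and 40865 probes had a coordinate on mm8, to which all positions refer. A probe was kept in a tissue if it was well above background on all 4 arrays of at least 1 of the 3 groups, and each gene was represented by its probe with the highest mean, which left 18299 genes in brain and 16365 in liver. Genes were told apart by the name in the file, so that 12 current symbols in brain and 10 in liver stand for a pair of features. Where such a symbol is named, the feature with that name in the file is meant.

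Differences between groups were tested with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), by a linear model over the 12 arrays of a tissue with moderated t-tests. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and errors of log2 differences are standard errors from the model. Differences between tissues were tested as the difference of differences over 14767 genes and all 24 arrays. Where a group had no array well above background, the difference is given as a lower bound of the fold change against the dimmest measurable level. A gene missing on some arrays after removal of outlier spots was tested on the rest, and the text gives the number of arrays where this affected a named gene. In each of 59 fixed gene lists at least 5 measured genes with a value on every array were required, which left 56 lists in brain and 55 in liver. The lists were tested with limma's camera at a set correlation between genes of 0.01 and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists.

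The distance of an animal from the controls was the number of genes at least 2-fold from the mean of 3 controls, averaged over the 4 sets of 3 for clones and taken against the other 3 for a control, and the root mean square of those log2 differences. The spread within a group was the root mean square difference of an array from the mean of the others in its group. Both were compared by exact two-sided permutation over 70 splits, for which the smallest possible p is 0.0286. For genes shared by the comparisons of CC and G20 with NC, the correlation and covariance of the fold changes were also computed in 20 simulations of unchanged groups against the same controls (seed 1) and in fits in which each comparison had its own controls. Neighbouring genes were counted within 1000000 bases, against random draws from the measured genes.

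Comparisons, their tests, the lists and all but 1 of the alternatives were chosen before the data were examined, while many tests of explanations were chosen afterwards, as said where they are given. Named genes were, for each comparison, the 8 highest and 8 lowest called genes with a gene symbol whose arrays did not overlap between groups, and up to 4 called members of each list that passed camera or had at least 3 called members. A fixed set of imprinted genes, Xist, Alb and Afp was always included. For the tissue difference the 5 highest and 5 lowest were taken. Not every gene named by this rule is printed, a few of them are not reported here, and genes outside it are said to have been chosen after their values were seen.

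Alternatives were array weights, another background correction (normexp, offset 50), all probes, no filter on dim probes, a filter requiring every array above background, a trended and robust variance, the replicate number as a block, median scaling, quantile normalization, the matrix values, fits with 1 array left out, fits with only the compared groups and camera with an estimated correlation. The normexp offset was added before each array was scaled. Dim genes therefore come out lower on brighter arrays, and their values after normexp depend on array brightness. A fit over the NC and G20 arrays alone, from the probe filter on, was added after the data had been seen. Whether replicate numbers pair the groups was checked by correlating residuals of arrays with the same number, which gave −0.23 to 0.13, and the groups were treated as unpaired. Brain and liver with the same number in the labels' titles correlated by 0.02 to 0.32, and an alternative treated them as one animal.

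The procedure was tested on simulated data with 200 changed genes. Of changes of 1 on the log2 scale 93.0% and 89.0% were recovered in brain (CC and G20) and 83.0% and 78.0% in liver, and of changes of 2 at least 96.0%. Between 7 and 16 unchanged genes were called as well. The simulated noise was normal, with each gene's spread from the model and no background floor. These shares therefore do not measure what is lost near background. For the tissue difference 92.5% of changes of 2 were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out.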

Results

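Gene expression was measured with single-colour microarrays in brain and liver of neonatal female mice, on 24 arrays. Each tissue had 3 groups of 4 arrays. NC animals were controls conceived by intracytoplasmic sperm injection, in which a sperm is injected directly into an oocyte. CC animals were clones derived from cumulus cells, the somatic cells that surround an oocyte. G20 animals were clones of the 20th generation of serial cloning, in which clones of one generation supply the nuclei for the next. The labels gave all animals the same cross of inbred strains as genetic background. The series asks whether faults of nuclear reprogramming build up when clones are cloned again, and each tissue therefore gave the comparisons of G20 with NC, CC with NC and G20 with CC.

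Signal differed between groups. In brain, 68.2% to 70.4% of probes were well above background on the NC arrays, 68.1% to 70.6% on the G20 arrays and 62.4% to 63.9% on the CC arrays. In liver the ranges were 57.7% to 59.6% in NC, 60.5% to 62.9% in G20 and 53.6% to 56.4% in CC. The 75th percentile of the scanner signal was 814.3 to 935.1 in brain NC, 402.1 to 465.3 in brain CC and 724.0 to 864.2 in brain G20, and 276.3 to 340.8, 239.0 to 268.8 and 438.7 to 561.4 in the corresponding liver groups. The NC and G20 arrays of liver were scanned in one session and those of brain in another 49 days later. The CC arrays of both tissues were scanned 221 days after the first session. Each group of each tissue had its own slide, so slide and group cannot be told apart anywhere. Scan session and group cannot be told apart in any comparison with CC. All G20 arrays carry one source name, and nothing but the numbers in their titles says that they came from separate animals. The p-values for G20 therefore measure the spread between these samples, which may be technical.

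In brain, G20 animals had higher levels of several imprinted genes that are read from the paternal copy. Plagl1, a zinc-finger regulator of growth, rose by 0.99 ± 0.08 (log2, SE, n = 4 per group, limma adjusted p = 0.000103). Zrsr1, an intronless gene inside Commd1 that encodes a splicing factor, rose by 1.02 ± 0.16 (limma adjusted p = 0.00984). Mcts2, an intronless gene inside an intron of H13, rose by 0.90 ± 0.17 (limma adjusted p = 0.0292). Impact, a regulator of translation, rose by 0.77 ± 0.12 (limma adjusted p = 0.01). H13, the host gene of Mcts2 and a signal peptide peptidase, fell by 1.93 ± 0.40 (limma adjusted p = 0.0381). The calls of Mcts2 and H13 were lost in 8 and 11 of 24 alternatives. Of the 28 measured paternally expressed imprinted genes 5 rose and none fell, against 12 and 0 adjusted over the list alone, with a median difference of 0.24. The list passed limma's camera test (adjusted p = 0.000134), and had an adjusted p = 0.632 with an estimated correlation. Igf2 differed by −0.17 (limma adjusted p = 0.556) and H19 by −0.17 (adjusted p = 0.725). Peg3 differed by −0.07 (limma adjusted p = 0.776), Snrpn by 0.12 (adjusted p = 0.708) and Nnat by 0.32 (adjusted p = 0.111). Xist, the RNA that coats the inactive X chromosome, differed by 0.37 ± 0.18 (limma adjusted p = 0.285).

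**Figure D1:**
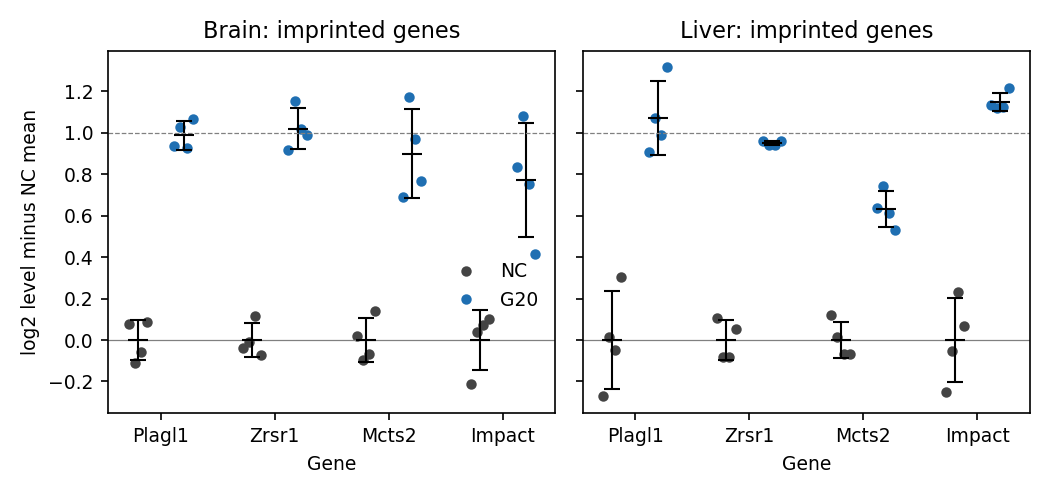
Levels of Plagl1, Zrsr1, Mcts2 and Impact in each NC and G20 array of brain and liver, as log2 level minus the NC mean; points are arrays, and bars the mean and SD of 4 arrays. In brain the G20 arrays lie between 0.41 and 1.17 and the NC arrays between −0.21 and 0.14; in liver they lie between 0.53 and 1.32 and between −0.27 and 0.31, and the dashed line marks a 2-fold difference.

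A stretch of chromosome 7 held several of the strongest increases in G20 brain. Between 59.0 and 63.0 Mb (mm8), around the imprinted cluster that holds Snrpn, Ndn and Ube3a, 10 of 25 measured features rose and none fell. They lie between 59103614 and 61810010, and the region was chosen after the values were seen. D0Kist2, listed as a long non-coding RNA (chromosome 7, 60968688 to 60968747), rose by 3.92 ± 0.29 (limma adjusted p = 3.23e-05, but 2.50 and not called after normexp). D7Ertd715e, a name of the Ube3a antisense transcript Snhg14, rose by 1.55 ± 0.31 (limma adjusted p = 0.0305, lost in 9 of 24 alternatives). A230057D06Rik (chromosome 7, 61584950 to 61585009) and A330076H08Rik were singled out after their values were seen. They rose by 3.51 ± 0.10 (limma adjusted p = 3.31e-09) and 1.79 ± 0.18 (adjusted p = 0.000403). The protein-coding genes of the cluster did not pass the test: Snrpn differed by 0.12, Snurf by 0.15, Ndn by 0.15, Magel2 by 0.34, Mkrn3 by 0.65 and Ube3a by −0.35.

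**Figure D2:**
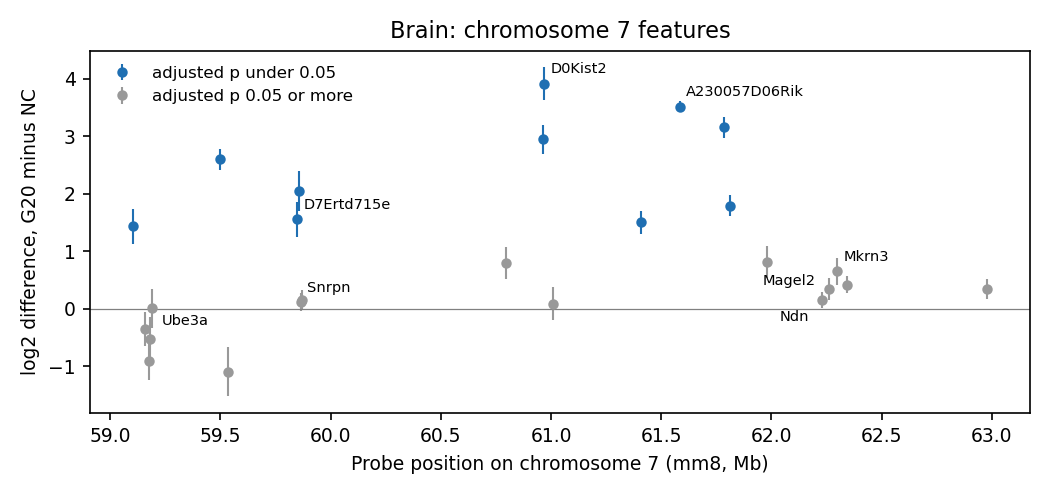
Difference between G20 and NC in brain (log2, with SE) for the 25 features measured between 59.0 and 63.0 Mb of chromosome 7 (mm8), by probe position. The 10 features in blue passed an adjusted p of 0.05, and all of them were higher in G20; grey features did not pass.

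Other genes called in G20 brain were of several kinds. Mbl2, a serum lectin, rose by 3.16 ± 0.69 (limma adjusted p = 0.0455, with 1 of 4 NC arrays well above background). Serpina1d, a protease inhibitor, rose by 2.09 ± 0.43 (limma adjusted p = 0.0374), and Cpb2, a plasma carboxypeptidase, by 1.63 ± 0.30 (adjusted p = 0.023). The calls of Mbl2, Serpina1d and Cpb2 were lost in 11 of 23, 10 of 24 and 7 of 24 alternatives. The liver products albumin (Alb) and alpha-fetoprotein (Afp) differed by 0.36 ± 0.45 and 0.36 ± 0.43 (limma adjusted p = 0.7 and 0.683). The transcription factor Elf4 was at least 5.56-fold higher (limma adjusted p = 0.0339, well above background on 3 of 4 G20 arrays and no NC array, lost in 9 of 21 alternatives). Xlr4b and Xlr3c, X-linked genes of a family whose copies resemble each other, fell by 2.41 ± 0.41 and 2.23 ± 0.35 (limma adjusted p = 0.0144 and 0.00984). Gcnt1, a glycosyltransferase, fell by 2.66 and Mcpt4, a mast cell protease, by 2.52 (limma adjusted p = 0.00315 and 0.0127, each well above background on 2 of 4 G20 arrays). The transporter Slc6a16 fell by 1.78 ± 0.16, the chemokine Ccl21a by 1.59 ± 0.30 and the G-protein regulator Rgs10 by 1.37 ± 0.11 (limma adjusted p = 0.000186, 0.0266 and 7.45e-05), and the call of Ccl21a was lost in 9 of 24 alternatives. After normexp Gcnt1 differed by −0.15, Mcpt4 by −0.39, Slc6a16 by −0.35 and Ccl21a by −0.57, Xlr4b by −1.65 and Xlr3c by −1.34, and Mbl2 by 1.44, Serpina1d by 1.36 and Elf4 by 1.21, with none of them called.

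Among fixed gene groups in brain, 10 of 56 lists passed camera between G20 and NC, and with an estimated correlation 0 did, at limma adjusted p = 0.632 or above. None of 14 erythroid genes passed over all genes, while 9 rose adjusted over the list alone, with a median of 0.48 (limma camera adjusted p = 0.000122; adjusted p = 0.632 with an estimated correlation). Of 27 hypoxia genes 1 rose, P4ha2, a collagen hydroxylase, by 0.76 ± 0.15 (adjusted p = 0.0337, lost in 11 of 24 alternatives), and 7 adjusted over the list alone (limma camera adjusted p = 0.000593; adjusted p = 0.864 with an estimated correlation). Of 17 microglia genes 1 fell, C1qb, a complement subunit, by 0.52 ± 0.11 (adjusted p = 0.0432, lost in 15 of 24 alternatives), and adjusted over the list alone 1 rose and 6 fell (limma camera adjusted p = 0.00388; adjusted p = 0.632 with an estimated correlation). The muscle myosins Myh1 and Myh8 fell by 0.94 and 0.65 (0.0236 and −0.26 after normexp, lost in 8 and 9 of 24 alternatives), the only 2 of 22 muscle genes called, also adjusted over the list alone (limma camera adjusted p = 0.0334; adjusted p = 0.864 with an estimated correlation). Further lists had no member called: hindbrain (median 0.40, 18 genes), choroid plexus (−0.34, 16 genes), glutamatergic cortex (−0.18, 23 genes) and interferon response (−0.12, 30 genes). They passed limma's camera at adjusted p = 0.0017, 0.00927, 0.00927 and 0.0334. Adjusted over the list alone, 1 hindbrain gene rose, 1 glutamatergic gene fell and none of the other lists' members passed. The adjusted p with an estimated correlation was 0.832, 0.864, 0.632 and 0.97.

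In all, limma called 324 of 18299 brain genes between G20 and NC (226 higher, 98 lower), of which 76 differed at least 2-fold. Scaling by the median gave 134 higher and 95 lower calls, and quantile normalization 169 and 120. After a different background correction (normexp), 2 genes were called and the median of all genes lay at 0.10. Without the filter on dim probes 141 were called, with the replicate number as a block 149, and with the NC and G20 arrays alone 155, of which 132 were among the 324. The count was 133, 144 and 156 without G20 replicates 1, 2 and 4, 153, 155 and 188 without NC replicates 1, 2 and 4, and 526 without G20 replicate 3.

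In liver, the 4 imprinted genes named above as higher in G20 brain were higher again. Impact rose by 1.15 ± 0.12 (limma adjusted p = 0.000457), Plagl1 by 1.07 ± 0.15 (adjusted p = 0.00227), Zrsr1 by 0.95 ± 0.16 (adjusted p = 0.00636). Mcts2 rose by 0.63 ± 0.14 (limma adjusted p = 0.0237), with 4 arrays per group. Dlk1, a Notch-like protein of fetal liver, rose by 1.11 ± 0.27 (limma adjusted p = 0.031, lost in 7 of 24 alternatives), and Cdkn1c, a maternally expressed inhibitor of the cell cycle, by 1.32 ± 0.35 (adjusted p = 0.0441). The groups overlapped for Cdkn1c, with NC replicate 4 at 6.105, the other NC arrays at 4.29 to 4.36 and the G20 mean at 6.09, and its call was lost in 15 of 24 alternatives. Snrpn and Snurf, which share a transcript, fell by 1.41 ± 0.36 and 1.43 ± 0.35 (limma adjusted p = 0.0385 and 0.0329). The groups overlapped for Snrpn, and the calls of Snrpn and Snurf were lost in 12 and 8 of 24 alternatives. Of 23 paternally expressed genes 6 rose and 2 fell, against 7 and 3 adjusted over the list alone (limma camera adjusted p = 0.0878; adjusted p = 0.538 with an estimated correlation). Of 27 maternally expressed genes 2 rose and 1 fell, against 2 and 2 over the list alone (limma camera adjusted p = 0.398). Igf2 differed by 0.04, H19 by −0.19, Peg3 by 0.14, Grb10 by −0.04 and Xist by 0.30 (limma adjusted p = 0.826, 0.292, 0.729, 0.889 and 0.12).

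Genes of fatty acid synthesis were lower in G20 liver. Thrsp, a lipogenic regulator, fell by 5.04 ± 0.75 (limma adjusted p = 0.0033), the desaturase Scd1 by 2.77 ± 0.69 (adjusted p = 0.0351), the acetyl-CoA carboxylase Acacb by 2.34 ± 0.40 (adjusted p = 0.00679) and the elongase Elovl5 by 1.67 ± 0.36 (adjusted p = 0.0188). The groups overlapped for Scd1, whose call was lost in 8 of 24 alternatives, and for Elovl5. Of 18 lipogenic genes 7 fell and none rose, with a median of −1.27, and 14 fell adjusted over the list alone (limma camera adjusted p = 2.95e-09; adjusted p = 0.538 with an estimated correlation). Of 39 genes of mature hepatocytes 6 fell and 1 rose, against 12 and 1 adjusted over the list alone, with a median of −0.25 (limma camera adjusted p = 0.000268; adjusted p = 0.566 with an estimated correlation). The apolipoprotein Apoc3 fell by 4.09 ± 0.55, the serine protease inhibitor Serpina3k by 4.54 ± 0.55, the cytochrome Cyp2c29 by 1.15 ± 0.15 and transthyretin (Ttr) by 0.63 ± 0.17 (limma adjusted p = 0.00174, 0.00109, 0.00174 and 0.0459). The call of Ttr was lost in 16 of 24 alternatives, and after normexp Ttr differed by −0.26 and Cyp2c29 by −0.61. Alb and Afp differed by 0.13 ± 0.09 and 0.10 ± 0.08 (limma adjusted p = 0.417 and 0.484).

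**Figure D3:**
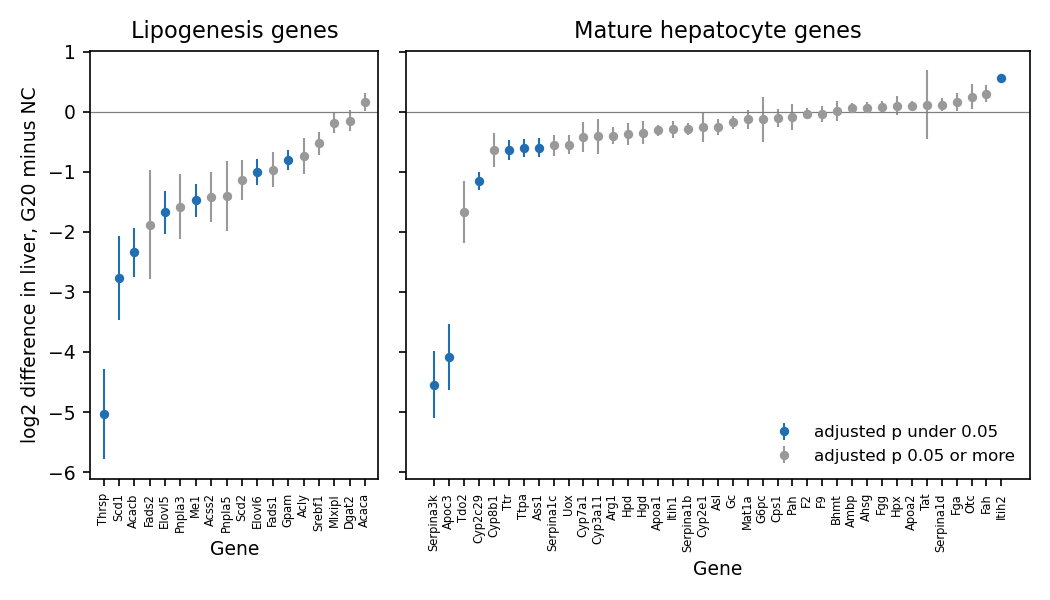
Difference between G20 and NC in liver (log2, with SE) for 18 lipogenic genes and 39 genes of mature hepatocytes, each in order of its difference; blue marks an adjusted p under 0.05. Lipogenic genes have a median of −1.27 and mature hepatocyte genes one of −0.25.

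The genes with the largest differences in G20 liver were of several kinds. Serpina6, which carries glucocorticoids in blood, rose by 4.99 ± 0.74 (limma adjusted p = 0.0033), Hamp, the iron hormone hepcidin, by 3.63 ± 0.44 (adjusted p = 0.00108). The protease inhibitor A2ml1 rose by 3.15 ± 0.28 (limma adjusted p = 0.000191) and Serpina7, which carries thyroid hormone, by 2.70 ± 0.36 (adjusted p = 0.00182). The troponin Tnnc1 rose by 2.63 ± 0.52, the vesicle protein Rab7b by 2.11 ± 0.49, the retinol dehydrogenase Rdh16 by 1.96 ± 0.31, and the desmoglein Dsg1c by 2.62 ± 0.43 with 1 of 4 NC arrays well above background (limma adjusted p = 0.0136, 0.0254, 0.00461 and 0.00533). After normexp Rdh16 and Dsg1c turned to −0.33 and −0.43, and Rab7b and A2ml1 differed by 0.48 and 1.65. The call of Rab7b was lost in 7 of 24 alternatives. The sulfotransferase Sult3a1 was at least 63.8-fold lower in G20, where it was not well above background (limma adjusted p = 0.00241). The proteinase inhibitors Mug1 and Mug2 fell by 5.34 ± 0.53 and 5.22 ± 0.54, and Serpina3c fell by 4.38 ± 0.51 (limma adjusted p = 0.000373, 0.000922 and 0.000963). The fatty acid hydroxylase Cyp4a12a fell by 4.82 ± 0.24 (limma adjusted p = 1.69e-06). The apolipoprotein Apoa4 fell by 4.65 ± 0.86 (limma adjusted p = 0.00982) with 1 of 4 G20 arrays well above background, a call lost in 1 of 23 alternatives. After normexp Apoa4 differed by −2.54, Sult3a1 by −3.25, Orm1 by −2.42 and Orm2 by −2.38. Mug1 and Mug2, Serpina3k and Serpina3c, and Cyp2a5 and its neighbour Cyp2a4 belong to families of closely related genes that a probe may not tell apart. Of 38 xenobiotic metabolism genes 5 rose and 7 fell, among them Cyp3a25 (−2.75) and Cyp2a5 (−1.98), against 7 and 8 adjusted over the list alone (limma camera adjusted p = 0.0475; adjusted p = 0.668 with an estimated correlation). Of 24 acute phase genes 3 rose and 4 fell, against 3 and 5 adjusted over the list alone, including Serpina3m (−4.14), Orm1 (−3.97) and Orm2 (−3.73, 3 of 4 G20 arrays). Their median was 0.06 and their mean −0.43 (limma camera adjusted p = 0.532; adjusted p = 0.91 with an estimated correlation).

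Genes of several further groups were called in G20 liver. Among growth hormone and IGF genes 5 of 18 fell and none rose, including Igf1 (−1.20 ± 0.22, limma adjusted p = 0.00968) and the signalling inhibitor Socs2 (−1.05 ± 0.20, adjusted p = 0.0113). After normexp Igf1 and Socs2 differed by −0.80 and −0.64, and were not called. Also lower were Igfbp5 (−1.01 ± 0.14, limma adjusted p = 0.00241) and Igfbp4 (−0.43 ± 0.11, adjusted p = 0.0449, lost in 11 of 24 alternatives and −0.11 after normexp). Adjusted over the list alone 1 rose and 5 fell (limma camera adjusted p = 0.176; adjusted p = 0.566 with an estimated correlation). Of 34 interferon response genes 5 fell, among them the transcription factor Irf9 (−0.998 ± 0.16, but −0.52 and not called after normexp), Mx1 (−0.95 ± 0.25, lost in 12 of 23 alternatives) and Igtp (−0.49 ± 0.13, lost in 13 of 24, overlapping, and 0.12 after normexp), and 6 adjusted over the list alone (limma camera adjusted p = 5.64e-07; adjusted p = 0.538 with an estimated correlation). Endothelial genes fell in 3 of 20 cases, Lyve1 by 0.75, Sox18 by 0.47 and Tie1 by 0.35, and in 6 adjusted over the list alone (limma camera adjusted p = 8.89e-05; adjusted p = 0.538 with an estimated correlation). The calls of Sox18 and Tie1 were lost in 9 and 11 of 24 alternatives, and Lyve1 differed by −0.31 after normexp. Of 28 stellate cell and fibroblast genes 4 fell and 1 rose, with Thy1 at −1.27 and Mgp at −1.12, against 8 and 2 adjusted over the list alone (limma camera adjusted p = 0.00312; adjusted p = 0.542 with an estimated correlation). Of 28 genes of the endoplasmic reticulum stress response 5 rose and none fell, among them Ddit4 (0.74), Pdia4 (0.55), Dnajb9 (0.47) and Herpud1 (0.36), and 7 adjusted over the list alone (limma camera adjusted p = 0.000219; adjusted p = 0.538 with an estimated correlation). The calls of Ddit4, Pdia4 and Herpud1 were lost in 7, 13 and 8 of 24 alternatives. Of 25 immediate early genes 3 rose, Ccn1 by 1.34, Zfp36 by 0.90 and Dusp1 by 0.69, and 9 adjusted over the list alone (limma camera adjusted p = 0.000129; adjusted p = 0.538 with an estimated correlation). These calls were lost in 9, 6 and 18 of 24 alternatives.

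Single clock genes were called in G20 liver in both directions. The repressors Nr1d1 and Nr1d2 rose by 1.93 ± 0.50 and 0.72 ± 0.19 and Per3 by 1.71 ± 0.38, while Cry1 fell by 0.66 ± 0.18 (limma adjusted p = 0.0385, 0.0437, 0.0228 and 0.0443), with Nr1d1 well above background on 3 and Per3 on 1 of the 4 NC arrays. The groups overlapped for Nr1d1 and Nr1d2. After normexp Nr1d1 and Per3 turned to −0.0405 and −1.07 and Nr1d2 differed by 0.15, and the calls of Nr1d1, Nr1d2 and Cry1 were lost in 12 of 23, 16 of 24 and 12 of 23 alternatives. Of the 16 clock genes 4 rose and 1 fell, against 6 and 3 adjusted over the list alone (limma camera adjusted p = 0.111; adjusted p = 0.629 with an estimated correlation). In all, 17 of 55 lists passed camera in liver and 0 did with an estimated correlation, where the adjusted p was 0.538 or above.

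limma called 1196 of 16365 liver genes between G20 and NC (705 higher, 491 lower), and 294 of them differed at least 2-fold (138 higher, 156 lower). Median scaling gave 376 higher and 739 lower calls, leaving the dim probes in gave 521 and 698, and normexp gave 845 and 4262. Array weights gave 3492 calls, and the replicate number as a block 722 (407 higher, 315 lower). The count was 643 and 607 without NC replicates 1 and 2 and 585 and 673 without G20 replicates 2 and 4.

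Genes called between G20 and NC in both tissues mostly moved the same way. Of 14767 features measured in both, 287 were called in brain and 945 in liver, and 66 in both, of which 57 moved in the same direction (39 higher, 18 lower) where independent lists would give 9.9. Brain and liver arrays with the same number correlated by 0.02 to 0.32 and may come from one animal, so the lists need not be independent. The 57 genes included Plagl1, Zrsr1, Mcts2, Impact and Per3 among the higher, and H13 and Gcnt1, which fell in liver by 0.98 and 3.94 in the fit over both tissues, among the lower. The 57 genes lay close together: 15 had another of the 57 within 1000000 bases, against a median of 4 and a 95th percentile of 10 among random draws of measured genes, a value reached in a share of 0.0025 of draws. Several of the neighbours were predicted genes of one repeated family at 3.7 to 5.8 Mb of chromosome 14, and without chromosome 14 the number was 10 of 49, against a median of 4, in a share of 0.0306 of draws.

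The effect of G20 differed between the tissues for 568 of 14767 genes when the difference itself was tested (318 with a higher effect in brain, 250 in liver). Mbl2 (brain minus liver 5.30 ± 0.82, limma adjusted p = 0.000769), Thrsp (4.46 ± 0.83, adjusted p = 0.00374), Ddo, an aspartate oxidase (3.099 ± 0.39, adjusted p = 0.00013), and Scd1 (3.02 ± 0.74, adjusted p = 0.0246) were among the highest. A2ml1 (−3.16 ± 0.35, limma adjusted p = 3.47e-05), Mcpt4 (−2.79 ± 0.48, adjusted p = 0.00211), Tnnc1 (−2.49 ± 0.56, adjusted p = 0.0141), Rtl3 (−2.27 ± 0.64, adjusted p = 0.0473) and the neurotensin receptor Ntsr1 (−2.15 ± 0.22, adjusted p = 3.47e-05) stood lowest. Snrpn differed between tissues by 1.53 ± 0.41 (limma adjusted p = 0.0377). Under median scaling the split was 339 and 150, without the filter on dim probes 703 and 267, and with array weights 1768 genes were called. After normexp 233 were called (201 and 32), Mcpt4, Rtl3 and Ntsr1 changed sign to 1.08, 1.25 and 0.85, and A2ml1 and Tnnc1 were not called at −1.09 and −1.25.

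Between CC and NC most brain genes differed in the scanner values, in a comparison where the groups also differ in scan session. Lars2, a mitochondrial tRNA synthetase, rose by 3.91 ± 0.53 (limma adjusted p = 4.04e-05), the liver transcription factor Creb3l3 by 3.35 ± 0.25 (adjusted p = 4.03e-07). Cpb2 rose by 3.19 ± 0.30 (limma adjusted p = 1.95e-06) and the telomerase RNA Terc by 2.95 ± 0.33 (adjusted p = 7.78e-06). Elf4 was at least 9.08-fold higher (limma adjusted p = 0.000145) and the zinc-finger gene Zfp345 at least 5.08-fold lower (adjusted p = 1.33e-07, but 0.44 on the log2 scale after normexp). Xlr3c fell by 2.40 ± 0.35 and the RNA-decay factor Cnot7 by 2.38 ± 0.15 (limma adjusted p = 7.25e-05 and 1.45e-07). Among imprinted genes, Peg3 fell by 1.47 ± 0.11, Plagl1 by 0.97 ± 0.08 and Snrpn by 0.76 ± 0.15 (limma adjusted p = 3.85e-07, 9.59e-07 and 0.000738). Alb and Afp rose by 1.74 ± 0.45 and 1.88 ± 0.43. Of 58 ribosomal protein genes 48 rose and 1 fell, of 47 oxidative phosphorylation genes 39 rose and 2 fell, of 21 glycolysis genes 16 rose and none fell, and of 22 histone genes 18 rose and 3 fell, with the same counts adjusted over the list alone. These 4 lists passed camera at limma adjusted p = 1.15e-07, 1.27e-05, 0.0146 and 0.0159, and had an adjusted p = 0.93 with an estimated correlation.

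In the deposited values, in which the CC arrays carry a further factor per probe that the 4 CC arrays of a tissue share, these brain differences were mostly smaller. Lars2 differed by 0.89 (limma adjusted p = 0.455), Peg3 by −0.11 (adjusted p = 0.692), Plagl1 by −0.02 (adjusted p = 0.93), Snrpn by −0.16 (adjusted p = 0.66), and Alb and Afp by 0.10 each. Creb3l3 rose by 1.41 (limma adjusted p = 0.0333), Cpb2 by 1.66 (adjusted p = 0.0354) and Mcts2 by 0.87 (adjusted p = 0.0424), and Xlr3c and Xlr4b fell by 2.44 and 2.80 (both adjusted p = 0.0149), all in the direction of the scanner values. Mcts2 and Xlr4b were added here after their values were seen. Between G20 and NC the deposited values of these 5 genes differed by nearly as much: 1.30 for Creb3l3, 1.61 for Cpb2, 0.88 for Mcts2, −2.25 for Xlr3c and −2.43 for Xlr4b. Over all features the deposited CC minus NC difference followed that of G20 with a slope of 0.518. How far the unexplained factor of the CC columns set these CC values is not known. On the scanner values limma called 12681 of 18299 genes (7593 higher, 5088 lower) and the median of all genes lay at 0.13. On the 16334 features with a deposited value on all 12 arrays it called 114 (44 higher, 70 lower). Of these, 107 were called in the same direction on the scanner values and 1 in the opposite one. Median scaling gave 9036 higher and 3859 lower calls with the median of all genes at 0.28, and leaving the dim probes in gave 15110 and 5095 at 0.45. Normexp gave 5332 calls with that median at 0.39.

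In liver, CC animals had 6659 of 16365 genes called against NC on the scanner values (3220 higher, 3439 lower), again with the scan session between the groups. Hamp rose by 3.70 ± 0.44 (limma adjusted p = 5.74e-05), the chaperone Dnajb8 by 6.50 ± 0.41 with 1 of 4 NC arrays well above background (adjusted p = 4.79e-07) and Elf4 at least 8.68-fold (adjusted p = 2.09e-05). The linker histone H1fx fell by 4.14 ± 0.39 (limma adjusted p = 9.64e-06), the sperm membrane gene Spaca4 by 3.95 ± 0.13 (adjusted p = 8.24e-09), and the olfactory receptor Olfr1153 was at least 30.4-fold lower (adjusted p = 2.6e-08). Igf2 fell by 1.43, Afp by 0.80 ± 0.08 and H19 by 0.52 ± 0.10. Alb differed by −1.32 ± 0.14, with a usable value on 1 of the 4 CC arrays. Plagl1 differed by −0.12 (limma adjusted p = 0.554), Dlk1 by −0.03 (adjusted p = 0.944) and Snrpn by 0.01 (adjusted p = 0.987). Lists that passed camera were neutrophil genes (11 of 19 fell, none rose), cholesterol synthesis (18 of 25 fell, 1 rose), ribosomal proteins (22 of 44 fell, 4 rose), mature hepatocyte genes (16 of 39 fell, 2 rose) and stellate cell genes (9 of 28 rose, none fell). Adjusted over the list alone the counts were 11, 20 against 1, 24 against 5, 17 against 2, and 7. The 5 camera tests gave limma adjusted p = 0.000528, 0.000528, 0.00293, 0.0186 and 0.0186, and adjusted p = 0.988 with an estimated correlation.

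The deposited liver values gave another picture of CC. Plagl1 rose by 1.07 (limma adjusted p = 0.00219) and Dlk1 by 1.13 (adjusted p = 0.0197), and Snrpn fell by 1.63 (adjusted p = 0.0198). Thrsp, chosen after its values were seen, fell by 5.02 (limma adjusted p = 0.00311) and Hamp rose by 3.14 (adjusted p = 0.00224). H1fx, Alb and Igf2 differed by 0.31, 0.01 and −0.02. On the 14234 features with a deposited value on all 12 arrays, 1200 were called between CC and NC (589 higher, 611 lower). Of these, 371 were called in the same direction on the scanner values and 155 in the opposite one. The deposited means of CC and G20 liver lay closer together than arrays of one group do: the SD over features of their difference was 0.0978, where the spread between replicates gives 0.191. The deposited CC minus NC difference followed that of G20 with a slope of 0.988 (r = 0.965 across genes, which are not independent replicates). In brain the SD was 0.189 against 0.151 and the slope 0.518. Scaling by the median gave 3961 higher and 2793 lower calls on the scanner values with the median of all genes at 0.10, leaving the dim probes in gave 6781 and 3258 at 0.23, and normexp gave 229 calls (32 higher, 197 lower) with that median at −0.10.

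Where a gene called between CC and NC by at least 2-fold had another probe, that probe often moved the other way. In brain the second probe moved in the same direction for a share of 0.649 of 717 genes (95% exact binomial interval 0.612 to 0.684) and in liver for 0.57 of 193 (0.497 to 0.641). For G20 against NC, whose arrays share a scan session, the share was 0.967 of 60 genes in liver (0.885 to 0.996) and 0.545 of 11 in brain (0.234 to 0.833). The 10 control transcripts added to every sample differed after scaling by a mean of 1.77 (log2, SD 0.603 over transcripts) between CC and NC in brain and 0.704 (SD 0.706) in liver. Between G20 and NC they differed by 0.606 (SD 0.272) in brain and −0.0464 (SD 0.158) in liver. Across the measured range their signal rose with dose at a slope of 0.81 to 0.89 on the CC arrays and 0.93 to 1.02 on all others.

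Between G20 and CC the scanner values called 12361 of 18299 genes in brain (5226 higher, 7135 lower) and 7361 of 16365 in liver (4030 higher, 3331 lower). In brain D0Kist2 was at least 19.4-fold higher in G20 (limma adjusted p = 2.44e-07), Plagl1 rose by 1.96 ± 0.08 (adjusted p = 4.35e-08), Peg3 by 1.40 ± 0.11 (adjusted p = 6.96e-07) and Cnot7 by 2.34 ± 0.15 (adjusted p = 2.33e-07). Prdm16, a regulator of fat and neural cells, fell by 4.00 ± 0.67 (limma adjusted p = 0.000233). Of these Plagl1 also rose in the deposited values, by 0.94 (limma adjusted p = 8.14e-05), and Prdm16 fell there by 3.43 (adjusted p = 0.0292), while Peg3 differed by 0.01 (adjusted p = 0.986) and Cnot7 by −0.0116. Prkca, a protein kinase, rose by 2.79 ± 1.07 (limma adjusted p = 0.0351, 3 of 4 G20 arrays), with one G20 array at 4.03 and the others at −1.83 or below, and differed by −0.25 in the deposited values and −0.46 after normexp. In liver Serpina6 rose by 5.42 ± 0.74, the bicarbonate transporter Slc4a7 by 4.43 ± 0.74, Igf2 by 1.47 ± 0.10 and Plagl1 by 1.19 ± 0.15 (limma adjusted p = 0.000134, 0.000562, 5.85e-07 and 7.5e-05). Cdkn1c rose by 1.23 ± 0.35 (limma adjusted p = 0.0134). Sult3a1 was at least 119-fold and Dnajb8 at least 114-fold lower, and Mug1 fell by 4.78 ± 0.53 (limma adjusted p = 6.7e-05, 2.37e-07 and 2.77e-05). In the deposited liver values limma called 0 of 14234 features between G20 and CC, and 0 had an unadjusted p under 0.05, where chance alone gives 711.7. Serpina6 differed by 0.30, Mug1 by 0.34 and Slc4a7 by −0.13. In brain 227 of 16334 were called, with 1755 at an unadjusted p under 0.05.

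Gene groups were tested on the scanner values alone. In brain 49 of 58 ribosomal protein genes were lower in G20 than in CC and 1 higher, 39 of 47 oxidative phosphorylation genes were lower and 1 higher, and 22 of 30 interferon genes were lower. Likewise 13 of 17 microglia genes were lower and 1 higher, 18 of 22 histone genes were lower and 2 higher, and 21 of 31 proteasome genes were lower and 4 higher. Adjusted over the list alone the lower and higher counts were 50 and 2, 40 and 1, 22 and 0, 13 and 1, 18 and 2, and 21 and 4. These 6 lists passed camera (limma adjusted p = 1.07e-08, 3.66e-06, 0.00535 for the next 3, and 0.0255), with adjusted p = 0.924 with an estimated correlation. In liver, stellate cell (16 of 28), interferon (17 of 34) and meningeal or pericyte genes (10 of 19) were lower with none higher. Endothelial genes were lower in 9 of 20 and higher in 1, and ribosomal protein genes were higher in 25 of 44 and lower in 4. Adjusted over the list alone the counts were 16, 17 and 10, then 13 and 1, then 25 and 4. Camera gave limma adjusted p = 0.000106, 0.00119, 0.0193, 0.0109 and 0.00281, with adjusted p = 0.975 with an estimated correlation. Median scaling gave 3650 higher and 9008 lower calls in brain, with the median of all genes at −0.27, and 2839 and 5172 in liver at −0.15. Leaving the dim probes in gave 5231 and 14457 in brain at −0.40 and 4138 and 10444 in liver at −0.27. Normexp moved the brain median to −0.26 with 3823 calls and gave 2221 in liver, and all probes gave 18581 in brain.

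The CC effect differed between tissues for 7980 of 14767 genes in the scanner values (5116 with a higher effect in brain, 2864 in liver). H1fx (brain minus liver 5.78 ± 0.48, limma adjusted p = 6.44e-09), the synaptotagmin Syt10 (5.48 ± 0.46, adjusted p = 7.91e-09), the kinase Mink1 (5.30 ± 0.37, adjusted p = 7.25e-10), Arl4d (5.06 ± 0.22, adjusted p = 9.23e-13) and Cdk5r2, an activator of a neuronal kinase (4.62 ± 0.31, adjusted p = 4.32e-10), stood highest. Dnajb8 (−3.18 ± 0.61, limma adjusted p = 0.000167), Wdr52 (−2.56 ± 0.57, adjusted p = 0.000692), Tfcp2 (−2.50 ± 0.37, adjusted p = 9.19e-06), the G-protein regulator Rgs4 (−2.27 ± 0.60, adjusted p = 0.00302) and Zfp385b (−2.19 ± 0.22, adjusted p = 8.74e-08) stood lowest. A second probe listed under the name Arl4d differed by −0.70. In the deposited values 976 genes were called (503 and 473), and H1fx, Dnajb8, Wdr52 and Rgs4 changed sign to −0.27, 3.65, 0.04 and 1.86. There Syt10, Mink1, Arl4d and Cdk5r2 differed by 0.0678, 0.58, 0.41 and 0.47 and were not called. After normexp Tfcp2 and Zfp385b were not called at −0.0598 and −0.40. Quantile normalization gave 4598 and 3478, and normexp moved the median of all genes to 0.33 with 1724 calls, against 0.16 in the scanner values and 0.23 under median scaling.

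The distance of each clone from the controls bears on whether differences grew with recloning, but the CC arrays also differ from the others in scan session. In brain, an average of 3026 ± 424 genes (SD, n = 4) lay at least 2-fold from the controls in CC animals, 333.8 ± 181 in G20 animals and 163.5 ± 57.6 in the controls themselves. By the scanner values G20 animals thus had fewer such genes than CC animals. The difference was −2692 (exact two-sided permutation p = 0.0286, the smallest that the 70 splits allow). In liver the numbers were 1600 ± 37.3 in CC, 662.6 ± 135 in G20 and 297.2 ± 124 in NC, and the difference between G20 and CC was −937.8 (exact permutation p = 0.0286). G20 lay farther from the controls than these lay from each other in liver (exact permutation p = 0.0286) but did not pass in brain (exact permutation p = 0.0571). The root mean square distance was 0.77 in CC, 0.36 in G20 and 0.27 in NC brain, and 0.69, 0.49 and 0.36 in liver, with G20 minus CC at −0.41 and −0.20 (both exact permutation p = 0.0286). With the deposited values the difference between G20 and CC was 85.5 genes in brain and −34.31 in liver (exact permutation p = 0.286 and 0.629), and 0.03 and −0.02 in root mean square distance (0.371 and 0.514). The deposited CC and G20 means of liver lay closer together than replicate spread gives (SD 0.0978 against 0.191). A liver difference near 0 follows from that and does not bear on recloning. In brain the deposited CC means lay between the other groups. The SD over features was 0.149 from the mean of NC and G20, 0.194 from NC and 0.189 from G20. How far the unexplained factor of the CC columns set the brain distance is not known, so it is no check on the scanner values either. After normexp the difference between G20 and CC was −1583 genes in brain and 1599 in liver (exact permutation p = 0.457 and 0.0286).

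**Figure D4:**
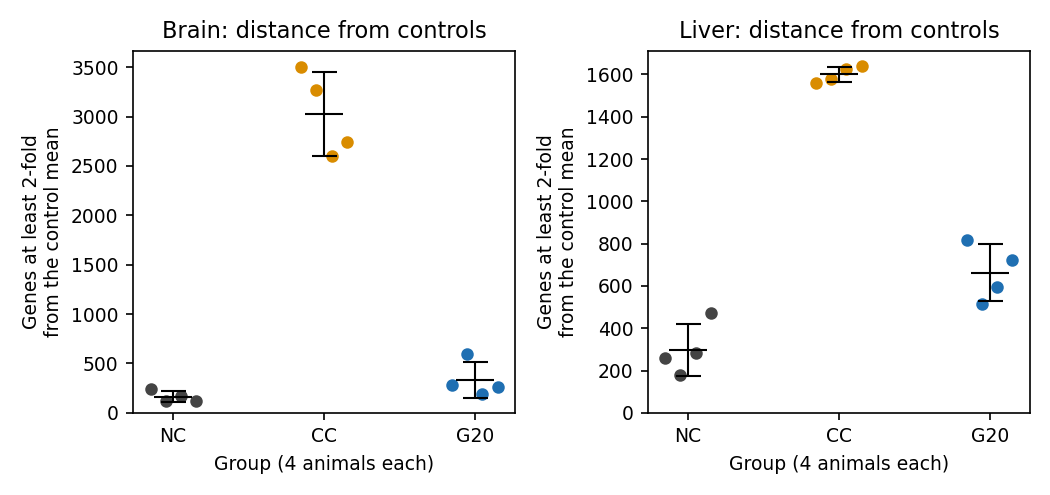
Number of genes at least 2-fold from the mean of the controls in each animal's scanner values, for brain and liver; points are animals, bars the mean and SD of 4. Brain CC animals lie between 2603 and 3497 and G20 animals between 191.8 and 598; liver CC animals lie between 1559 and 1639 and G20 animals between 514.8 and 819.5.

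Some genes were called for both CC and G20 against NC, in comparisons that use the same control arrays. In brain 201 genes were called in the same direction in both (158 higher, 43 lower) and 53 in opposite directions, where independent lists would share 121. In liver 375 were called in the same direction (235 higher, 140 lower) and 158 in opposite ones, where independent lists would share 241.9. The fold changes correlated across genes by 0.272 in brain and 0.15 in liver, below the 0.50 and 0.497 that shared controls gave in simulated unchanged groups. Their covariance was 0.056 in brain and 0.0388 in liver, against 0.0127 and 0.0199 in the simulations. With the controls divided between the comparisons, it was 0.0235 to 0.0511 in brain and 0.0016 to 0.0305 in liver, and the correlation 0.0971 to 0.229 and 0.0054 to 0.115. In liver the lowest of these lie near 0. In both tissues the divided controls still came from the same slide. An offset of the NC slide would thus enter both comparisons, and dividing the controls cannot remove it. How much the clones shared beyond their controls stays open in both tissues. With the deposited values 72 genes were shared in brain and 908 in liver, and normexp left 0 and 10. The deposited CC and G20 means of liver lay closer together than replicate spread gives (SD 0.0978 against 0.191). The 908 therefore largely repeat the G20 calls and do not measure what the clones shared. How far the unexplained factor of the CC columns set the 72 in brain is not known. In brain median scaling left 125 and leaving the dim probes in 75.

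Clones did not differ detectably from controls in how much animals of one group varied. The mean distance of an array from the others of its group was 0.27 ± 0.03 in NC, 0.29 ± 0.02 in CC and 0.28 ± 0.04 in G20 brain (SD, n = 4), and 0.36 ± 0.03, 0.39 ± 0.06 and 0.31 ± 0.09 in liver. Exact two-sided permutation tests gave p = 0.314 for CC against NC, 0.857 for G20 against NC and 0.543 for G20 against CC in brain, and 0.486, 0.371 and 0.171 in liver. The median over genes of the SD within a group was not tested. It was higher in the clones, at 0.121 in NC, 0.136 in CC and 0.148 in G20 brain, and 0.149, 0.181 and 0.165 in liver. After normexp, brain CC and G20 varied more than NC by 0.46 and 0.39 and liver G20 less than CC (−0.40), each at an exact permutation p of 0.0286, and leaving the dim probes in gave −0.04 for CC against NC in brain (exact permutation p = 0.0286).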

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

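A difference between tissues was tested for each named gene, and 29 of 47 named genes measured in both tissues differed for CC and 36 of 84 for G20, with 7980 and 568 of all genes called. For CC against NC the effect in brain minus that in liver was 2.68 for Afp, 3.06 for Alb (1 liver CC array with a value), 5.06 for Arl4d, 4.62 for Cdk5r2, 2.69 for Cpb2, 3.06 for Creb3l3, −2.09 for D4Ertd681e, −3.18 for Dnajb8, 1.47 for Duox2, 5.78 for H1fx, 1.23 for Igf2, −1.50 for Itgb8, 1.82 for Kif12, 3.55 for Lars2, 5.30 for Mink1, 3.81 for Olfr1153, −1.92 for Peg3, −0.86 for Plagl1, −1.53 for Rex2, −2.27 for Rgs4, 2.50 for Spaca4, 5.48 for Syt10, 1.30 for Terc, −2.50 for Tfcp2, 3.03 for Vmn1r46, −2.56 for Wdr52, −1.35 for Zfp345, −2.19 for Zfp385b and −1.30 for Zfp943. The genes picked as the most different between tissues stand here by their choice.

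For G20 against NC the effect in brain minus that in liver was −3.16 for A2ml1, 2.56 for Acacb, −1.34 for Acat2, −1.47 for Amy2a5, 0.97 for Cdkn1a, 1.77 for Cpb2, 2.26 for Cyp2a4, 2.35 for Cyp2a5, 3.099 for Ddo, 2.42 for Elf4, 1.74 for Elovl5, 0.86 for Hsd17b7, −1.08 for Hspb8, 1.26 for Igf1, 1.23 for Igfbp5, −1.18 for Islr, 0.45 for Kcnq1, 5.30 for Mbl2, −2.79 for Mcpt4, 1.73 for Me1, −2.15 for Ntsr1, 1.23 for Phlda3, −1.28 for Rgs10, 2.69 for Rgs5, −2.27 for Rtl3, 3.02 for Scd1, 1.97 for Serpina1d, −1.28 for Slc6a16, 1.525 for Snrpn, 1.59 for Snurf, 0.94 for Socs2, 0.88 for Tal1, 4.46 for Thrsp, 1.52 for Thy1, −2.49 for Tnnc1 and −1.90 for Xlr4b.

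An array that stood far from the other 3 of its group was found for 36 of 394 sets of a named gene and a group, where chance marks about 1 in 20, or 19.7, and for 1 of 48 sets of array measures. That measure was the SD over probes of the log2 ratio of deposited to scanner value, 0.657 on liver CC replicate 1 against 0.627 to 0.631 on the others. The levels that follow are log2 relative to the array's 75th percentile. In liver NC, replicate 4 stood apart for Apoa4 (−2.97, others −0.54 to −0.26), Cdkn1c (6.105, others 4.29 to 4.36), Ddit4 (4.46), Mug1 (1.49, others 3.64 to 3.80), Mug2 (−0.24), Ndn (−1.60) and Pnliprp1 (−0.0623), replicate 3 for Cdkn1a (0.94) and Dnajb8 (−3.97), and replicate 1 for Mx1 (−2.52). In liver G20, replicate 4 stood apart for Dlk1 (6.71), Hamp (6.21), Impact (1.99) and Serpina3c (−2.05), and replicate 1 for Gcnt1 (−1.38), Herpud1 (5.10) and Snurf (−1.73). In liver CC, replicate 1 stood apart for Cdk5r2 (−1.86) and Rusc1 (0.34), and replicate 2 for Pced1b (1.11). In brain NC, replicate 3 stood apart for D7Ertd715e (−1.28) and Mbl2 (−5.99), replicate 2 for Serpina1d (−3.55) and replicate 1 for Xist (3.23). In brain G20, replicate 1 stood apart for A230097C02 (−0.44), H13 (−1.40, others −0.39 to −0.28) and Tbx21 (−2.68), replicate 2 for Alb (−3.56) and Peg10 (−4.50), replicate 3 for Myh1 (−3.89), Prdm16 (−3.58) and Xist (3.51), and replicate 4 for Prkca (4.03, others −2.10 to −1.83). In brain CC, replicate 1 stood apart for Mest (2.67) and Plagl1 (2.35), and replicate 3 for Lars2 (8.25).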

How the results depend on the processing

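The results below were computed again with 1 choice changed at a time. The list tests had 2 alternatives, the overlap and the spread 6 each, and the genes called in both tissues, their neighbours, the chromosome 7 region, the other probes and the splits had none. For the changes below the cause was not tested unless stated. Among named genes the values kept their direction and side of the threshold in 815 of 951 fits for G20 against NC in brain and 1783 of 2126 in liver, 663 of 725 and 666 of 703 for CC against NC, 665 of 721 and 664 of 698 for G20 against CC, and 272 of 300 and 322 of 336 for the tissue differences of G20 and CC. For G20 against NC most of the rest lost the threshold with their direction kept (129 in brain and 325 in liver). A gene called in neither fit whose sign differs is not counted as reversed. Array weights, a trended and robust variance and fits without single arrays reversed no value. Signal over background limited the tests to the 18299 brain and 16365 liver genes that passed the filter on dim probes.

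With the series matrix values, whose CC columns carry a further factor per probe, the G20 minus CC difference in root mean square distance became 0.0343 in brain (exact permutation p = 0.371) and −0.02215 in liver (exact permutation p = 0.514), and in genes at least 2-fold away 85.5 (exact permutation p = 0.286) and −34.31 (exact permutation p = 0.629). Counts of called genes became 116 in brain and 1390 in liver for CC against NC, 232 and 32 for G20 against CC and 976 for the tissue difference of CC. These keep features with some values missing, while the report's counts of deposited values use features with a value on all arrays. The overlap became 72 in brain and 908 in liver. The liver distances and overlap here follow from deposited CC means that lay closer to G20 than replicate spread gives, and are no check on the scanner values. How far the factor of the CC columns set the brain distances and overlap is not known, so these are no check either. Reversed for CC against NC were Mest (−0.0874), Nr2f1 (0.37) and Zfp943 (0.0595) in brain, and Alb (0.006), Dlk1 (1.13), Dnajb8 (−1.85), Eml6 (−0.45), Evx2 (−0.70), H1fx (0.31), Itgb8 (−1.75), Pced1b (−0.20), Plagl1 (1.07), Slc4a7 (0.92), Snrpn (−1.63), Syt6 (−0.67) and Vmn1r46 (0.32) in liver. Reversed for G20 against CC were Afp (0.22), Alb (0.20), Cnot7 (−0.0116), Igf2r (0.0835), Lars2 (0.24), Mlstd1 (−0.0825), Nr2f1 (−0.46), Prkca (−0.25), Zfp125 (0.0466) and Zswim1 (−0.0795) in brain, and Apoa4 (1.03), Apoc3 (0.25), Gcnt1 (0.10), H19 (−0.0328), H1fx (−0.30), Mug1 (0.34), Rusc1 (−0.17), Slc4a7 (−0.13), Snrpn (0.20) and Vmn1r46 (−0.33) in liver. In the tissue difference of CC, Dnajb8 (3.65), H1fx (−0.27), Rgs4 (1.86) and Wdr52 (0.038) reversed.

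With normexp, the G20 minus CC difference in root mean square distance became −0.3707 in brain (exact permutation p = 0.371) and 0.107 in liver (exact permutation p = 0.0571), and in genes at least 2-fold away −1583 (exact permutation p = 0.457) and 1599 (exact permutation p = 0.0286). Called genes became 5332 in brain and 229 in liver for CC against NC, 3823 and 2221 for G20 against CC, 2 and 5107 for G20 against NC, and 1724 and 233 for the tissue differences of CC and G20. The overlap became 0 in brain and 10 in liver. The within-group spread differed by 0.4605 for brain CC against NC, 0.3933 for brain G20 against NC and −0.4031 for liver G20 against CC. Reversed were Axl (−0.0492), Dsg1c (−0.43), Gpx2 (−0.61), Gsta2 (−0.81), Igtp (0.12), Nr1d1 (−0.0405), Per3 (−1.07) and Rdh16 (−0.33) for G20 against NC in liver, Myh1 (0.0236) in brain, D4Ertd681e (0.61), Mlstd1 (0.18) and Zfp345 (0.44) for CC against NC in brain, and Prkca (−0.46) for G20 against CC in brain. In the tissue differences Dnajb8 (0.64) and Wdr52 (0.66) reversed for CC, and Mcpt4 (1.08), Ntsr1 (0.85) and Rtl3 (1.25) for G20.

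With quantile normalization, Grb10 (0.19) in brain and H19 (−0.22) in liver reversed for G20 against CC, and Ndn (−0.0174) and Nnat (−0.26) for CC against NC in brain, while 3 lists passed camera for CC against NC in liver and 10 for G20 against CC in brain. With an estimated correlation 0 lists passed camera in each of the 6 comparisons. Without the filter on dim probes, where more genes are tested, called genes became 20205 in brain and 10039 in liver for CC against NC, 19688 and 14582 for G20 against CC, 141 for G20 against NC in brain and 970 for the tissue difference of G20. The brain overlap became 75, and the spread of brain CC against NC −0.0432 (exact permutation p = 0.0286, over scores that depend on each other). With all probes 18581 were called for G20 against CC in brain, and with median scaling the brain overlap became 125. With array weights 3492 genes were called for G20 against NC in liver and 1768 for its tissue difference. With only the compared groups in the fit 153 were called for G20 against NC in brain. With the NC and G20 arrays alone, chosen after seeing the data, 155 were called in brain and 1208 in liver.

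With the replicate number as a replicate block, 149 genes were called for G20 against NC in brain (99 higher, 50 lower) and 722 in liver (407 higher, 315 lower), 12526 and 6067 for CC against NC and 12170 and 6860 for G20 against CC. With the animal as a replicate block across tissues, 8311 and 624 were called in the tissue differences of CC and G20. In the exact paired sign-flip test, where the smallest possible p is 0.125, the G20 minus CC differences kept their values, −0.4082 and −0.2031 in root mean square distance and −2692 and −937.8 in genes in brain and liver, at p = 0.125 each.

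With 1 array left out, the G20 minus CC difference in root mean square distance ranged from −0.4357 to −0.3865 in brain and −0.2219 to −0.1859 in liver, and in genes from −2834 to −2537 and −1011 to −888.5. Called genes ranged from 11990 to 12964 in brain and 5574 to 7048 in liver for CC against NC, 11658 to 12431 and 6308 to 7437 for G20 against CC, and 133 to 526 and 585 to 1403 for G20 against NC. They ranged from 7579 to 8241 for the tissue difference of CC and 396 to 713 for that of G20.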

Other observations

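Further single genes were called in G20 liver against NC. The digestive enzymes Amy2a5 and Pnliprp1, best known from the pancreas, rose by 1.65 ± 0.30 and 1.18 ± 0.31 (limma adjusted p = 0.00908 and 0.0414, Pnliprp1 with overlapping groups and lost in 14 of 24 alternatives), and of 14 exocrine genes 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.983; adjusted p = 0.986 with an estimated correlation). The detoxifying enzymes Gsta2 and Gpx2 rose by 1.73 ± 0.38 and 0.75 ± 0.15 (limma adjusted p = 0.0206 and 0.0149, Gsta2 well above background on 3 of 4 NC arrays), but turned to −0.81 and −0.61 after normexp. Of 25 oxidative stress genes 3 rose and 1 fell, also adjusted over the list alone (limma camera adjusted p = 0.983; adjusted p = 0.986 with an estimated correlation). The p53 targets Phlda3 and Cdkn1a fell by 0.88 ± 0.15 and 0.73 ± 0.15 (limma adjusted p = 0.00746 and 0.017; −0.39 and −0.41 after normexp), and of 25 such genes 2 rose and 2 fell, against 3 and 2 adjusted over the list alone (camera adjusted p = 0.21; adjusted p = 0.538 with an estimated correlation).

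Single genes of vessel walls, blood, cholesterol synthesis and bile transport were called as well. The pericyte gene Rgs5 fell by 2.50 ± 0.39 and the transporter Slc6a13 by 0.75 ± 0.12, while Islr rose by 0.93 ± 0.13 (limma adjusted p = 0.00429, 0.00519 and 0.00233), and after normexp Slc6a13 and Islr differed by −0.28 and 0.38. Of 19 meningeal and pericyte genes 1 rose and 2 fell, against 3 and 4 adjusted over the list alone (limma camera adjusted p = 0.0335; adjusted p = 0.538 with an estimated correlation). The embryonic globin Hba-x rose by 1.90 ± 0.49 and the blood transcription factor Tal1 fell by 0.53 ± 0.10 (limma adjusted p = 0.0388 and 0.013; 0.21 and −0.20 after normexp, and Hba-x, with overlapping groups, lost in 12 of 24 alternatives), the only 2 of 27 erythroid genes called, against 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.634 with an estimated correlation). In cholesterol synthesis Acat2 rose by 0.80 ± 0.20 and Hsd17b7 fell by 0.75 ± 0.18 (limma adjusted p = 0.0352 and 0.0287; Acat2 lost in 9 of 24 alternatives, Hsd17b7 at −0.36 after normexp), 1 each way of 25 genes, also adjusted over the list alone (camera adjusted p = 0.00237; adjusted p = 0.668 with an estimated correlation). The bile pigment exporter Abcc2 fell by 0.83 ± 0.15 (limma adjusted p = 0.00906; −0.46 after normexp), the only gene called of 15 in bile acid transport, also over the list alone (camera adjusted p = 0.000129; adjusted p = 0.538 with an estimated correlation).

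For the genes called between CC and NC on scanner values, the tests of a session effect common to both tissues, of dimmer signal and of cloning itself were chosen only after the result was seen. A probe-specific effect of the scan session predicted that another probe of the same gene would move the same way in a share well below that for G20 against NC, and it is undecided: in liver the share was 0.57 (0.5699) against 0.967, but in brain 0.649 of 717 genes against 0.545 of 11 (interval 0.234 to 0.833). Over all called genes the share in brain was 0.566 of 4676 for CC (0.5515 to 0.580) against 0.702 of 94 for G20 (0.599 to 0.792). In liver it was 0.51 of 2302 (0.489 to 0.531) against 0.8375 of 363 (0.795 to 0.874). At this cut, which the prediction did not name, the CC share was lower in both tissues, with intervals apart. An effect of the CC session common to both tissues is undecided at a correlation of 0.2876 across genes between tissues. Dimmer signal with a flatter scale on the CC arrays is undecided: quantile normalization left a share of 0.8678 of the brain calls, but normexp left 0.415 of them and 0.0342 of those in liver, and the control transcripts had a flatter slope on the CC arrays (0.81 to 0.89). Cloning itself is undecided: a share of 0.05631 of the liver calls recurred the same way in G20, which a difference between the kinds of clone would also give.

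For the higher Plagl1, Zrsr1, Mcts2 and Impact in G20, all tests but that of a strain variant under the 4 probes were chosen only after the result was seen. Activity of both parental copies, the biological explanation, is undecided: 7 of 8 intervals at 95% include a log2 difference of 1, while liver Mcts2 (0.32 to 0.95) does not. Scaling or background correction of the arrays is excluded for the choices tried, as median scaling, quantile normalization and normexp kept at least 0.9405 of the mean difference (0.94, and 0.98 after normexp). After normexp the brain calls nevertheless ended (limma adjusted p = 0.152, 0.0904, 0.662 and 0.796, with 2 brain genes called in all). The log2 differences in brain were then 0.86 ± 0.15 for Plagl1, 0.93 ± 0.14 for Zrsr1, 0.78 ± 0.20 for Mcts2 and 0.67 ± 0.22 for Impact. A strain variant under the measured probe is undecided because only 1 of the 4 genes had a different probe, and for Plagl1 alone it is excluded, since its other probe gave 1.0677. A general relaxation of imprinting by more than 0.5 in both tissues is excluded in brain, where the whole paternally expressed list had a median of 0.23 and a 75th percentile of 0.42 (0.4186), but not in liver (0.23 and 0.63), and a weaker one stays open.

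For the lower lipogenic and mature hepatocyte genes in G20 liver, the tests of the share of hepatocytes and of scaling were chosen only after the result was seen. A lower share of hepatocytes would raise the marker lists of other liver cells and is undecided: 5 of 5 such lists had medians below 0 (−0.26 to −0.02), but close to 0 and over members going both ways. A lower share alone would lower hepatocyte genes alike. Alb and Afp, named in advance, differed by 0.13 and 0.10, while the called lower members had a median of −1.47. A lower share alone thus would not give the large falls, and a small change of share stays open. Median scaling and quantile normalization left a share of at least 0.9752 of the median difference of the called lower members. Median scaling moves all genes of an array alike, so it could hardly have removed a difference this large. The median was −1.47 in the main fit, −1.55 after median scaling, −1.43 after quantile normalization and −1.21 after normexp. Each choice tried thus left the fall, and other effects of scaling were not tested. One outlying animal is excluded: with any array left out 9 to 19 members were called lower, and at least 8 of the 14 called with all arrays (Fasn among them, which lacks a value on some array and is outside the counts of the lists). Less milk fat reaching the liver, put forward as a biological explanation, is undecided. The median of its fatty acid oxidation list was 0.109, and the list did not differ detectably from the other genes (limma camera adjusted p = 0.934 with an estimated correlation). No value in these files measures feeding.

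The predictions behind these tests changed in places after results were visible. A further pattern, the genes called in both tissues and a genome shared by the G20 animals, had been written down beforehand and was taken out only to keep to 3 patterns, and its neighbour count stands in the report. The prediction for a lower share of hepatocytes was reworded and then replaced with the values known, each time with the verdict excluded, and stands here as first written, undecided. The test of a relaxation of imprinting was moved, with the values known, from the list without the 4 genes to the whole list and bound to more than 0.5. The tests of dimmer signal and of background correction were widened to normexp after its values were known, and the verdict on dimmer signal moved from excluded to undecided. The comparison with G20 in the test of other probes had been predicted but was at first not applied, and applying it moved that verdict from fits to undecided. The test of the Plagl1 probe alone was added after the 4-gene version had left 3 genes without another probe.

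All 35 ways to divide the 8 arrays or animals of a comparison into 4 and 4 were fitted, and for genes called only the real split, 1 of 35, gave a count as large. The real split was also the split by slide, and with CC against another group by scan session. An effect of slide or session would therefore give the same result. For CC against NC it called 12681 in brain and 6659 in liver, against at most 2 and 8 in any other split, for G20 against NC 324 and 1196 against 51 and 0, for G20 against CC 12361 and 7361 against 37 and 0, and for the tissue differences of CC and G20 7980 and 568 against 1 and 1. For gene lists passing camera, chance is not excluded. As many lists as in the real split passed in 25 splits for CC against NC in brain (4 lists, highest other 16) and 32 in liver (5, highest other 20). The numbers were 21 splits for G20 against NC in brain (10, highest other 23) and 6 in liver (17, highest other 19), and 29 for G20 against CC in brain (6, highest other 25) and 33 in liver (5, highest other 21).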
